A study of Drosophila melanogaster with 4 samples.

How the data were processed

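Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map the Drosophila Myc protein, the product of the gene diminutive (dm), in whole wandering larvae at the end of larval life. The labels describe 4 libraries from an inbred yellow, cinnabar, brown, speck strain. There are 2 libraries precipitated with a rabbit polyclonal antibody raised against Drosophila Myc and 2 libraries of input DNA. The sex of the larvae was not recorded. The labels do not say whether the 2 libraries of a kind came from separate collections of larvae.

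The data analysed here are 1 list of peaks for the whole series. Each peak has a start, an end and a score. The deposited file was written with MACS as its source and on FlyBase Release 5, per the file headers and the source column. The submitters' processing notes list CASAVA 1.7.0.2 and 1.7.0.3, BWA, MACS2 and the genome build BDGP5, without saying what each was used for. The significance threshold, any filter, and whether the authors pooled the 2 ChIP libraries are not given in the sources used here. The deposited score of each peak is the peak caller's own value. Its scale is named in no header, so it served to order and split peaks, and to compare medians between sets of peaks, within this list. No ratio of scores is given, since the scale may be logarithmic. The other deposited columns used are positions, which count from 1. Peaks carry consecutive numbers with no gaps.

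No value in the list belongs to a single library, and no read counts were analysed here. The sequencing depth is therefore unknown, no spread between replicates could be computed, and ChIP replicate could not be set against ChIP replicate. Every p-value given here describes how the peaks lie along the genome in this 1 list. None of them measures how a repeat of the experiment would differ.

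A genome sequence and gene annotation of Release 5 were not used here. The planned tests of promoter position, of gene lists and of the Myc and Max binding word therefore were not run, peaks were not assigned to genes, and features are named by Release 5 coordinates. A gene table of Release 6 served in 1 place, for gene names and gene order only, and none of its positions was compared with a peak. The rule for named peaks was fixed before the data were examined. With no annotation of the build, it took the 10 peaks with the highest score. Other features that are named were chosen after their values were seen, and the text says so.

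Peak density was computed per Mb from the first base of a sequence to the end of its last peak, since sequence lengths are not in the list. X and the 4 long autosome arms (2L, 2R, 3L, 3R) were compared over full bins of 500 kb, by 10000 permutations of the bins between X and the autosomes. The 95% interval of the ratio came from resampling the bins. Median scores and widths were compared with the peaks of a bin kept together. Chromosome 4 was compared with 10000 random windows of its own length on the long arms, and its intervals with runs of as many consecutive intervals there. The 1 Mb at each end of the long arms was compared with the same windows after 10000 circular shifts of the peaks along each arm. These are ends of the assembled arms, and the heterochromatin scaffolds are listed apart from them. Intervals between peaks were compared with 1000 random placements of the same peaks along the same arm, which kept their widths and the smallest observed interval of 50 bp. Scores of neighbours were compared with 1000 permutations of the scores within each arm. The median width and score of peaks outside the arms were compared with those on the arms by 10000 permutations of peaks, which treats peaks as independent, and widths within 5 score classes by 1000 permutations. Each peak on U and Uextra was also set against the 50 arm peaks nearest in score, with 1000 random draws of 1 matched peak each. Close pairs were also compared with 1000 random placements of the peaks inside their own stretches of 100 kb. The number of the 100 strongest arm peaks on X was tested with an exact binomial test. The tests by random windows, shifts and placements are called position permutations. All tests were two-sided, and the 31 p-values of the comparisons were adjusted together by the Benjamini-Hochberg method; those of the alternatives and of the tests of explanations were not part of them. Only the number of peaks and the density over the arms were planned before the data were examined. The density was planned with Fisher's exact test of genes with a peak, which needs an annotation, and the permutation of bins took its place. The other tests were chosen after the list was seen. The smallest p that these draws can give is 0.002 for placements and for scores of neighbours, 0.001 for widths within classes, 0.0002 for shifts and 0.0001 for permutations of bins or peaks.

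The tests were tried on simulated lists modelled on the 7768 peaks of the long arms, 20 lists for each setting. Apart from the effect that was set, simulated peaks were placed uniformly along each arm. The deposited peaks are more clustered, with a variance of peaks per 100 kb of 2.76 times the mean, against 0.88 times in random placement. The rates of calls below therefore need not hold for them. An X density set 1.2 times higher was called at p of 0.05 or below in 20 of 20 lists, and an equal density in 0 of 20. A density at the centromeric arm ends set to 0.5 of the rest was called in 20 of 20 lists, and an equal one in 1 of 20. An equal median score on X was called in 3 of 20 lists, and uniform spacing in 2 of 20 for intervals of 1 to 5 kb. For intervals under 500 bp against placement within 100 kb, uniform spacing was called in 1 of 20 and added close pairs in 20 of 20. Those added pairs gave a median excess of 7.07 times, larger than the 2.53 times of the deposited peaks. How often an excess of the smaller size would be called is not shown. Alternatives were the stronger part of the peaks (score at or above the median of 61.16), peaks merged within 100 bp or 1 kb, other bin and window sizes, each arm left out, and a row of wide peaks on 2L left out. The work was done with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.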

Results

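Myc is a basic helix-loop-helix transcription factor that drives cell growth, and Drosophila has a single Myc gene. The study asked where the protein sits on the chromosomes of wandering larvae, a stage at which polyploid larval tissues and dividing imaginal discs are both present. The design set 2 libraries precipitated with an anti-Myc antibody against 2 libraries of input DNA. Its outcome is 1 list of regions in which the authors' peak caller scored the ChIP signal above background.

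The list holds 8614 Myc peaks on 13 sequences of Release 5, and the peaks cover 8.10 Mb in all. The 6 chromosome arms carried 7867 of them, or 91.3%. The remaining 747 lay on unplaced or heterochromatic scaffolds. The median width of all peaks was 722 bp, with an interquartile range from 436 to 1151 bp. The authors' score ran from 6.58 to 1011.32 with a median of 61.16. Only 283 peaks scored above 500. Stronger peaks were wider, with a Spearman's rho of 0.81 across peaks, which are not independent replicates (permutation p = 0.001, the smallest that 1000 permutations give, adjusted p = 0.0041). Both values come from the same peak caller and the same signal. A link between them may be built in, and the permutation cannot tell. The strongest 10% by score had a median width of 1538.5 bp, against 269 bp for the weakest 10%.

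The 10 strongest Myc peaks were spread over X and 3 of the 4 long autosome arms. The strongest of all lay on 3L from 22400522 to 22401739 and scored 1011.32. The next lay on 2L from 14233601 to 14234981, with a score of 988.67. On 3R, the peak from 10918703 to 10921878 scored 971.90 and was 3176 bp wide. X carried 4 of the 10. Its strongest peak, from 17400738 to 17402171, scored 963.90, and the one from 20127432 to 20128895 scored 930.38. The other X peaks of this set began at 1832959, with a score of 924.02, and at 14968142, with a score of 914.84. On 3R, peaks from 20655149 to 20656374 and from 303999 to 306066 scored 925.32 and 921.42. The last of the 10, on 3L from 19055210 to 19056848, scored 881.81. None of the 10 was on 2R, 4 or an unplaced scaffold. Among the 100 strongest arm peaks, 21 were on X, which holds 18.6% of all arm peaks (exact binomial test, p = 0.52, adjusted p = 0.62), 28 on 3R, 19 on 2L, 18 on 3L, 13 on 2R and 1 on chromosome 4.

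The first comparison asked whether the chromosome arms carried Myc peaks at the same density. X carried 66.2 ± 22.4 peaks per Mb (mean ± SD over 44 bins of 500 kb) and the 4 long autosome arms 65.7 ± 22.4 (191 bins). The ratio of X to autosomes was 1.01, with a 95% interval from 0.90 to 1.12 (permutation p = 0.89, adjusted p = 0.92). Among single arms the mean density over full bins ran from 63.5 per Mb on 3L to 70.1 per Mb on 2R. No difference among the 5 long arms beyond the spread between their bins was detected (permutation p = 0.65, adjusted p = 0.72). The median score was 65.1 on X and 61.9 on the autosome arms (permutation p = 0.38, adjusted p = 0.49). The median width was 775 bp on X and 744 bp on the autosome arms (permutation p = 0.14, adjusted p = 0.21).

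**Figure D1:**
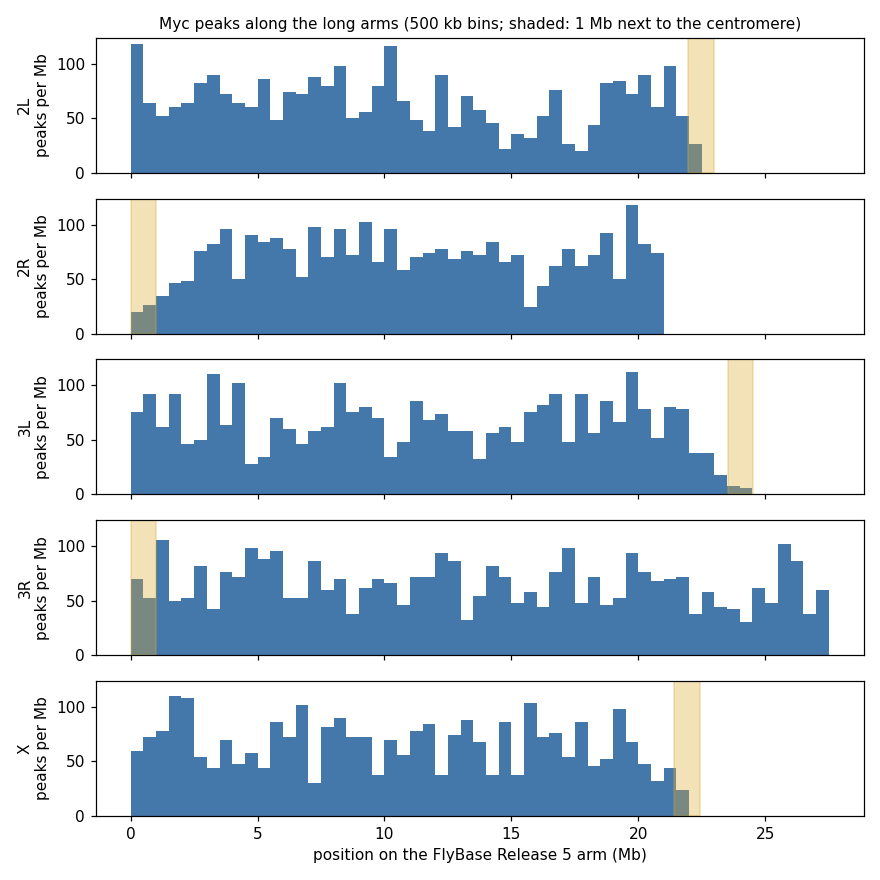
Peaks per Mb in full bins of 500 kb (bars) along the 5 long arms of Release 5. The horizontal axis is position in Mb. The part-filled last bin of each arm is not drawn. The shaded band is the 1 Mb at the centromeric end of the assembled arm. Density in that band falls to 8 per Mb on 3L and stays at 61 per Mb on 3R.

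Chromosome 4, a small and largely heterochromatic autosome, carried slightly more Myc peaks per Mb than any long arm, within the range of windows of its length on them. It had 99 peaks, or 73.3 per Mb against 63.4 on 3L and 69.9 on 2R, and 7.87% of its span was covered, against 5.80% on 3L and 6.63% on 2R. Random windows of its length on the long arms held a median of 92 peaks, with 95% of them between 42 and 121 (position permutation, p = 0.73, adjusted p = 0.78). Its median score of 80.4 lay within the range of 41.25 to 94.67 that held 95% of those windows (position permutation, p = 0.23, adjusted p = 0.32). Peaks on chromosome 4 lay closer together. There, 28 of 98 intervals between neighbours were under 1 kb, or 28.6%, against a median of 14.3% in runs of as many intervals on the long arms (position permutation, p = 0.012, adjusted p = 0.021).

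Myc peaks thinned out at the centromeric ends of the assembled long arms. The 1 Mb windows at the centromeric ends of the 5 long arms held 133 peaks together, or 26.6 per Mb, against 67.0 per Mb over the rest of these arms. The ratio was 0.40 (position permutation, p = 0.0002, the smallest that the shifts give, adjusted p = 0.0031). The window held 8 peaks on 3L, 20 on X, 21 on 2L and 23 on 2R. The arm 3R was the exception, with 61 peaks and a density 0.94 times that of the rest of the arm. The heterochromatin scaffold 3RHet, listed apart from that arm, held 15 peaks, or 6.31 per Mb. The exception therefore covers the assembled arm only. The peaks in these windows had a median score of 76.1, against a median of 62.4 over shifted windows (position permutation, p = 0.10, adjusted p = 0.16), and of 73.2 against 61.9 without 3R, which gave 61 of the 133 peaks (position permutation, p = 0.22). By arm, the medians in the windows were 99.3 on 2R, 95.6 on 3L, 78.2 on 2L and 77.4 on 3R, above the 62.0, 59.5, 60.5 and 66.1 of the whole arms. On X the median was 47.2, below the 65.1 of the whole arm. At the telomeric ends, 371 peaks gave 74.2 per Mb, 1.14 times the density of the rest (position permutation, p = 0.25, adjusted p = 0.33). The smallest number in a telomeric window was 58, on 3R, and the largest was 91, on 2L.

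Along the arms, Myc peaks were more clustered than in random placement and left long stretches empty. Random placement treats all positions of an arm alike. Uneven genes or read coverage along the arms were not taken into account, so the cause of the empty stretches was not tested. Of 7763 intervals between neighbouring peaks on the long arms, 1162 were under 1 kb, or 15.0%, against a median of 6.43% in random placement (range 5.63% to 7.60%, position permutation p = 0.002, the smallest that 1000 placements give, adjusted p = 0.0041). This excess, 2.33 times random placement, was 1.17 times among the stronger part of the peaks by score and then missed the threshold (position permutation, p = 0.060). Intervals of 1 to 5 kb made up 29.7%, against 22.9% in random placement, and the median interval was 6107 bp against 9953 bp (both position permutation p = 0.002, adjusted p = 0.0041). At the other extreme, 134 intervals were longer than 100 kb, where random placement gave a median of 7 and at most 17 (position permutation, p = 0.002, adjusted p = 0.0041). The longest stretches without a peak were 350.1 kb on 2L, from 16910552 to 17260652, 332.3 kb on X, from 14141852 to 14474156, and 331.6 kb on 3L, from 13506738 to 13838369. On 3R the longest was 254.5 kb and on 2R 225.5 kb. The variance of the number of peaks per 100 kb was 2.76 times its mean, against 0.88 times in random placement (position permutation, p = 0.002, adjusted p = 0.0041). That is 3.14 times the value of random placement, and 1.87 times for the stronger part of the peaks. Where peaks are clustered, leaving some out lowers this ratio in itself. The lower value therefore does not show that stronger peaks were less clustered.

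**Figure D2:**
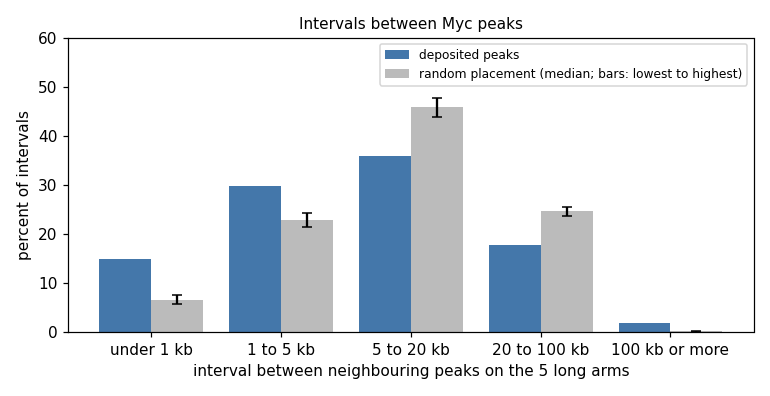
Percent of the intervals between neighbouring peaks on the 5 long arms by length class, for the deposited peaks and for 1000 random placements (bar: median; whiskers: lowest to highest). Intervals under 1 kb make up 15.0% against 6.43%, and those of 5 to 20 kb 35.9% against 46.0%.

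Very close neighbours had scores below those of permuted pairs. Over 7021 pairs of neighbours 500 bp or more apart, Spearman's rho between their scores was 0.02 (permutation p = 0.054, adjusted p = 0.093). The weaker peak of these pairs had a median score of 31.3, against 27.6 in permuted pairs, and the stronger one 137.4, against 133.4 (both permutation p = 0.002, adjusted p = 0.0041). This is not a separate result, since scores were permuted within arms and low scores in close pairs leave higher ones for the rest. Over the 840 pairs less than 500 bp apart, Spearman's rho was −0.22 (permutation p = 0.002, adjusted p = 0.0041). In these close pairs the weaker peak had a median score of 13.6, against 27.6 in permuted pairs, and the stronger one 94.6, against 133.8 (both permutation p = 0.002, adjusted p = 0.0041).

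The widest peaks on the arms were named after their values were seen. A single peak on 2L from 5221224 to 5234974 extended over 13.8 kb with a score of 243.75. One on 2R from 9469179 to 9479704 extended over 10.5 kb with a score of 467.49. A peak on 3L from 18981487 to 18990251 was 8.77 kb wide and scored 535.53. A different arrangement stood out at the base of 2L, also singled out after the values were seen. Between 21416849 and 21539494, a stretch of 122.6 kb, 23 peaks wider than 3000 bp followed one another. Their starts lay a median of 5043 bp apart. Of the 22 steps, 21 ran from 4811 to 5149 bp, with a mean of 5021 ± 94.7 bp (SD), and the remaining step was 13956 bp. The 23 peaks were alike in width, from 3253 to 4317 bp with a median of 3965 bp, and scored from 105.92 to 209.25 with a median of 143.26. A further 6 narrower peaks with a median score of 14.3 lay among them. The row held 10.4% of the 222 arm peaks wider than 3000 bp. The other 199 had a median score of 305.4, and the next longest chain of such peaks with starts less than 20 kb apart had 3 members.

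**Figure D3:**
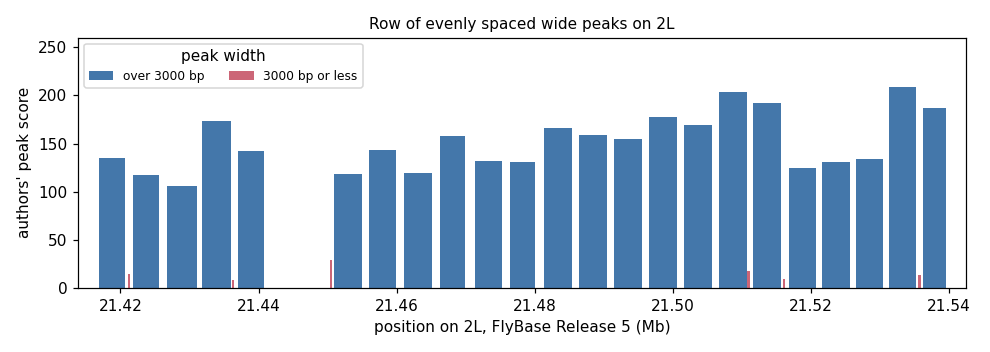
Peaks of the row at the base of 2L, drawn to scale along Release 5 (horizontal axis, Mb) with the authors' score as height; blue bars are wider than 3000 bp and red bars are narrower. The 23 wide peaks recur every 5043 bp (median) apart from 1 step of 13956 bp.

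Sequences outside the arms carried few Myc peaks. The list holds no read coverage, so few peaks there need not mean little binding. The 5 heterochromatin scaffolds held 63, from 6.31 per Mb on 3RHet to 35.3 per Mb on XHet, which rests on 3 peaks. Their median score was 64.2, against 62.9 for the arm peaks (permutation p = 0.93, adjusted p = 0.93), and their median width was 706 bp, against 751 bp (permutation p = 0.62, adjusted p = 0.72). U and Uextra, which collect scaffolds not assigned to a chromosome, held 86 and 598 peaks, or 8.58 and 20.6 per Mb. Peaks on Uextra were narrower than arm peaks, with a median of 601.5 bp against 751 bp (permutation p = 0.0001, adjusted p = 0.0031), and scored lower, with a median of 51.4 against 62.9 (permutation p = 0.0092, adjusted p = 0.018). They were narrower also within 5 score classes with equal shares of the arm peaks, by a mean ratio of 0.77 (permutation p = 0.001, adjusted p = 0.0041). In the highest class the median width was 804 bp for 36 Uextra peaks and 1416.5 bp for 1574 arm peaks, but the median scores in that class also differed, at 257.6 and 319.4. Set against the 50 arm peaks nearest in score, Uextra peaks had a median width ratio of 0.79 (permutation p = 0.002), and 475 of 598 were narrower than the median of their matched peaks. In the highest class the matched ratio was 0.62. The widest Uextra peak was 1427 bp, against 13751 bp on the arms. The lengths of the scaffolds collected in Uextra were not used, so how far they limit peak width is unknown. Peaks on U had a median width of 527.5 bp (permutation p = 0.0004, adjusted p = 0.0041) and a median score of 43.7, against 62.9 on the arms (permutation p = 0.066, adjusted p = 0.11). Matched in score in the same way, their median width ratio was 0.91 (permutation p = 0.042, unadjusted), and 51 of 86 were narrower than the median of their matched peaks. U also held the widest peak of the whole list, named after its value was seen. This peak, from 2166369 to 2183108, was 16.7 kb wide and scored 278.93, and its neighbour from 2153172 to 2166184 was 13013 bp wide and scored 163.66.

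**Figure D4:**
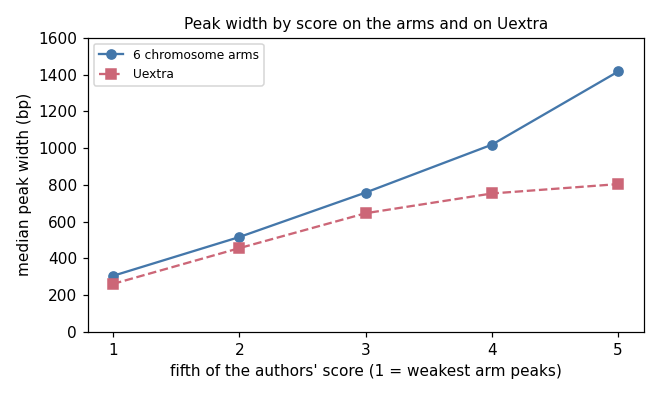
Median peak width in bp (points) in 5 classes of the authors' score (horizontal axis, 1 the weakest), set to hold equal shares of the arm peaks, for the 6 chromosome arms and for Uextra. Widths lie close in the lowest class, at 305 and 261 bp, and far apart in the highest, at 1416.5 and 804 bp.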

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

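For the number of peaks, the stronger part by score, the arms alone and merging within 100 bp were planned, and for the density on X the stronger part; all other alternatives were chosen after seeing the data. The number of peaks was 8614, 7867 on the arms alone, 8374 with peaks within 100 bp merged and 8585 without the row on 2L, and 4307 in the stronger part by construction. The ratio of X to autosome density crossed 1 with 200 kb bins (0.993) and with 1 Mb bins (0.9995), with neither value past the threshold. The number of peaks on chromosome 4 was 1.08 times that of random windows, and 0.91 times with peaks within 1 kb merged, neither past the threshold. The excess of intervals under 1 kb was 2.33 times random placement, and 1.17 times in the stronger part, where it missed the threshold (position permutation, p = 0.060). In pairs less than 500 bp apart the weaker peak had a median score of 13.6, below the cut of 61.16. The cut therefore takes at least 1 member from most of these pairs. Whether this accounts for the whole drop was not tested. The other 30 of 35 alternatives kept the direction and the side of the threshold, or a count within 1.5 times. Among them, the ratio of density at the centromeric arm ends ran from 0.27 without 3R to 0.57 with 2 Mb windows. No paired analysis was possible because no value in the list carries a replicate number. For the same reason no replicate was left out. The alternatives set beforehand for promoter share, genes with a peak, gene lists and the binding word, and the density per gene on each arm, were not run. The unknown depth leaves open how many weaker regions fell below the authors' threshold.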

Other observations

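Apart from the count of histone units in the gene table and the placement of peaks within 100 kb stretches, whose predictions were written before their results were seen, the tests in this part were chosen only after the result was seen.

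The row of 23 wide peaks at the base of 2L may mark the tandem array of replication-dependent histone genes, which are expressed in S phase and whose products package newly made DNA. A gene table of Release 6, used for names and order only, lists 23 His1, 23 His2B, 23 His3, 22 His4 and 20 His2A genes on 2L, all in 1 run with at most 2 other genes between neighbours, so 23 units with a His1 gene face 23 wide peaks. The longest run of any other group of like-named genes on that arm was 17, of small nucleolar RNA genes, leaving out names that mark no family (gene numbers, and long, antisense and small non-coding RNAs) and histone pseudogenes; which names to leave out was chosen after the table was seen. The match rests on the number of units, since the position of the array in Release 5 was not used. The step of 13956 bp follows 5 wide peaks. No stretch between neighbouring His1 genes holds more than 5 genes of any kind, small RNA genes included. That number, also the median, is reached in 19 of 22 stretches, and the fifth stretch holds 4. A count of genes cannot show a length in bp or added sequence without genes. The order of the genes therefore neither gives nor excludes a counterpart to the step. Reads of many genomic copies piled onto the assembled ones stay open as another source of the signal and were not tested, since the list holds no input level.

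A higher density of peaks over stretches of 100 kb did not account for the pairs of peaks less than 500 bp apart. Intervals under 500 bp made up 10.5% of the intervals on the 5 long arms, 2.53 times the 4.16% of random placement inside the same stretches (highest of 1000 placements 4.79%, position permutation p = 0.002). A candidate explanation is that the peak caller listed shoulders of 1 enriched region as separate peaks. Over the 6 arms, the median score of the weaker member lay at the 11.9 percentile of arm peaks, against 29.2 in permuted pairs. That of the stronger member was also lower, at 60.9 against 70.8 (both permutation p = 0.002). The prediction written for shoulders was a lower score of the weaker member alone. What listing 1 region as separate peaks does to the score of the stronger member was not tested. Shoulders therefore stay open, as do pairs of separate regions. No biological explanation was tested, since a genome sequence and gene annotation of Release 5 were not used.

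The thinning of peaks at the centromeric ends of 4 of the 5 long arms has several possible explanations. An even loss of mappable reads in repeat-rich sequence was taken to predict weaker peaks there. Weakened peaks may also fall below the authors' unknown threshold and leave the list. The median score therefore cannot decide this, and it stays open. Without 3R, the median score lay at the 53.8 percentile of arm peaks, against 49.5 in shifted windows (position permutation p = 0.22), with X below its arm and 2L, 2R and 3L above theirs. Stretches to which no reads could be assigned would remove peaks without weakening the rest; they were not tested, since the list holds no read coverage. A lower density of active genes near these arm ends also stays open and was not tested.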
